A study of Mus musculus with 12 samples.

How the data were processed

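RNA was measured in 12 cochlear libraries of C57BL/6J mice aged 12 months, 4 each from control, coffee and GTE mice. Per the labels' protocols, total RNA was taken with Trizol and libraries were made with a stranded mRNA kit (TruSeq), which selects polyadenylated RNA. The deposited values are FPKM, 1 value per Ensembl gene and library, and per the submitters' processing notes the tools were Trimmomatic, HISAT2, Cufflinks and HTSeq with the mouse build mm10. The roles and versions of these tools, the annotation release, the strand setting of counting and any filter are not given in the sources used here. Because the strand setting is unknown, values of genes that share exon bases with another measured gene are uncertain. Among the genes named in the text this held, by share of exon bases, for Epyc (40.6%), Ceacam16 (23.2%), Atp2a1 (21.9%), Adora1 (20.1%), Mpo (15.0%), Prtn3 (9.2%), Nr1d1 (8.5%), Myh1 (8.1%), Wnk4 (7.4%), Jun (7.3%), Plk1 (7.1%), Col9a3 (6.1%), Bmp6 (5.7%), Ace and Mybpc1 (5.6% each), Tiparp (5.1%), Gclm (4.7%), Manf (4.7%, 4.1% and 0.4% with 3 genes), Usp18 (4.4%), Eln (3.3%), Kcnq1 (3.0%), Spsb1 (2.3%), Ahr (2.1%), Eng (1.5%), Rag1 and Irf7 (1.2% each) and Cp (1.1%). Mt2 had the largest share, 73.5%, and Arntl, Bcl6, Dusp1, Plin4, Prkab2 and Sptb had at most 0.4%. Near-identical copies of a gene are named where known, and no search for them was made.

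The FPKM values moved in steps. Multiplied by the exon length of each gene in GENCODE M21 (the same mm10 coordinates) and by 1 factor per library, they came out whole within 0.01 fragments in every library for 31897 of 34538 genes (92.4%), and for the other 2641 at another gene length. The recovered FPKM denominators were 20526024 to 24835934 fragments. The recovered fragments summed to 105.59% to 106.24% of the denominator, so the denominator is not their plain sum, and the reason was not found. The value of 3 fragments on a gene of 2000 bases, a floor that covers counting error only, was 0.060 to 0.073 FPKM. Mitochondrially encoded genes took 7.8% to 14.6% of the summed FPKM of a library. No pair of the 12 files held identical values. A gene symbol was found for 34459 of the Ensembl identifiers (99.77%), and 79 had none.

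Groups and replicate numbers came from the sample titles, which do not say that the replicates of a group are separate animals. The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), as deposited and without further scaling. The fit held the 3 group means over all 12 libraries, used empirical Bayes moderation with a mean-variance trend, and tested the 15854 genes with at least 1 FPKM in at least 4 of the libraries. Benjamini-Hochberg adjustment was applied within each comparison, with a threshold of 0.05. A fold change on this scale understates the change of genes with low values. The comparisons were coffee against control, GTE against control, GTE against coffee, and any difference between the 3 groups (moderated F). The median log2 difference of all tested genes was 0.010, 0.007 and -0.002 in the first 3. Exact permutation tests of single genes and list means were two-sided over the 70 arrangements of 8 libraries, so their smallest p is 0.0286.

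There were 37 gene lists, for cochlear cell types, for other tissues a dissected cochlea can carry, such as marrow, bone, muscle, fat and middle ear epithelium, and for pathways that caffeine, catechins or ageing could touch. They held 644 distinct genes, of which 641 were matched in the files (Myo15a, Ahsp and Hjv were not) and 598 were tested. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 37 lists. Camera with an estimated correlation, fry and the exact permutation test of list means are given beside it. Within a list, limma p-values were also adjusted over the list alone. The design, the lists, the rule for named genes and most alternative settings were fixed before the data were examined. The voom fit on recovered fragments, the fit without coffee 1, coffee 4 and GTE 1, the exact tests of list means, the lists of glucocorticoid response, clock arm, brown fat, pituitary and nociceptor genes, and the choice of which lists are described at length came afterwards.

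The rule for named genes took, per comparison and direction, the 10 genes with the largest log2 change among those past the threshold or, with fewer than 5 of these, the 5 smallest p-values, with a mean of at least 2 FPKM in the higher group and a symbol that is not a clone or predicted name. It added up to 4 members with the smallest p of each list described, and genes fixed for every comparison, among them Myo7a, Slc26a5, Otof, Kcnq1, Gjb2, Coch, Tubb3, Bmp6, Nqo1, Cyp1a1, Adora1 and Adora2a. Some genes that the rule took are not reported here.

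Alternatives tried were other pseudocounts, filters and scalings, a fit of only the 8 libraries compared, other variance models, sample weights, the replicate number as a block, the mean of the myeloid marrow list as a covariate, and leaving out each library in turn. Comparisons that share the controls were set beside 100 simulations of unchanged groups against the same controls. The scripts were tested on simulated data for coffee against control, with 15854 genes of which 200 were changed, in 20 simulations. The 200 were drawn from genes outside the lists with higher mean values, so the shares found do not cover genes with low values. Where the noise was independent between genes, 60.4%, 85.7% and 96.7% of the genes changed 1.5, 2 and 4 times were found, with a mean of 9.8 false genes and 0 false lists. Where the libraries varied together as measured, 55.4%, 83.4% and 96.7% were found with a mean of 2 false genes, while camera at the preset correlation called a mean of 10.2 unshifted lists. In that setting a list shifted by -0.5 was found in 100% of simulations at the preset correlation and in 0% with an estimated correlation. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the figures. The sequencing reads were not analysed here.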

Results

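The cochlea, the hearing organ of the inner ear, was profiled by RNA sequencing in wild-type C57BL/6J mice, an inbred strain known for early age-related hearing loss. The 12 libraries fell into 3 groups of 4 libraries each. Control mice had plain drinking water, coffee mice had black coffee at 0.1% in the water, and GTE mice had green tea extract at 0.006%. Treatment ran from 3 to 12 months of age, when the tissue was taken. The deposited values were FPKM (fragments per kilobase of gene length, scaled to the depth of the library) for 34538 Ensembl genes, of which 15854 were expressed highly enough to be tested. The FPKM denominators of the 12 libraries, recovered from the steps in the values, were 20526024 to 24835934 fragments. With these, 3 fragments on a gene of 2000 bases correspond to 0.060 to 0.073 FPKM. Pearson correlations of log2(FPKM + 1) between libraries of a group ran from 0.953 to 0.975 in control, 0.938 to 0.970 in coffee and 0.920 to 0.973 in GTE. The labels do not say that the 4 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be in part technical. Fold changes are given on the log2(FPKM + 1) scale, which understates the changes of genes with low values. Levels are mean FPKM ± SD (n = 4 libraries per group).

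The comparison of coffee with control asked which cochlear transcripts differed after long-term coffee drinking. Mean values of the gene lists of the stria vascularis, of spiral ligament fibrocytes and of pigment cells were lower in coffee, whereas those of dividing cells and of myeloid marrow cells were higher. These 5 list calls of camera did not hold beyond its preset correlation (adjusted p from 0.618 to 0.627 with an estimated correlation). In simulated libraries that varied together as measured, an estimated correlation found a list shifted by -0.5 in 0% of simulations. The preset correlation called a mean of 10.2 unshifted lists there. Losing a call with the estimated correlation thus does not tell a real shift of that size from a false call. Serpinh1, which encodes the collagen chaperone HSP47 of the endoplasmic reticulum, was the only gene that passed the limma test over all 15854 genes. It fell by 0.77 ± 0.09 (SE) on the log2 scale, from 160.1 ± 10.7 FPKM in control to 93.5 ± 4.88 in coffee (adjusted p = 0.0474), and every coffee library lay below every control library (exact permutation p = 0.0286, the smallest that 4 libraries against 4 can give, two-sided). Serpinh1 (ENSMUSG00000070436) lies on chromosome 7 of mm10 from 99345376 to 99353239, on the minus strand. The coffee libraries also differed from the controls in 3175 genes at an unadjusted p under 0.05, where chance gives 793 on average. That count scatters widely by chance, because genes vary together. Unchanged groups, simulated with libraries varying as measured, gave a median of 337.5 and an upper interval end of 2804, which is not a maximum. Of the 3175 genes, 1467 were higher and 1708 lower, so that 46.2% were higher, against 32.5% after quantile normalization and 70.1% with the marrow list as a covariate. Leaving out coffee 1 or coffee 4 brought the 3175 to 1567 and 1677. The Serpinh1 call was lost without any of 9 libraries, with adjusted p of 0.257, 0.241, 0.309 and 0.114 without controls 1 to 4, 0.279, 0.143 and 0.160 without coffee 1, 2 and 4, and 0.142 and 0.0756 without GTE 2 and 4. Serpinh1 passed in 10 of 28 alternatives, with a log2 difference from -0.81 to -0.72 and an adjusted p from 0.0151 to 0.391. Among the others were the replicate block (adjusted p = 0.0954), only the 8 libraries compared (0.0842) and the marrow covariate (0.102). The count was 98 genes without coffee 3 and 28 without GTE 1, and without coffee 2 it was the antibody segment Ighv1-22 alone (2.05, adjusted p = 0.0195), named after its value was seen.

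The other genes with the smallest p-values did not pass in limma (all adjusted p = 0.199). On the higher side in coffee stood Gatm, the first enzyme of creatine synthesis, at 33.4 ± 4.27 FPKM against 17.9 ± 3.89 in control (log2 difference 0.88 ± 0.16 SE), the forkhead factor Foxn2 (0.65), the clathrin adaptor subunit Ap1s2 (0.50), the AMP-activated kinase subunit Prkab2 (0.40) and Lnpk, a shaper of endoplasmic reticulum junctions (0.37). On the lower side stood the tetraspanin Tspan11 at 5.28 ± 0.704 against 9.57 ± 0.338 (-0.76), glutaminyl cyclase Qpct (-0.69) and Pttg1ip (-0.38). Among genes fixed for every comparison, the outer hair cell motor prestin, Slc26a5, was at 1.499 ± 0.779 FPKM in coffee, 2.04 ± 0.429 in GTE and 3.03 ± 0.195 in control. The gap junction gene Gjb2 was at 231.3 ± 61.9, 330.7 ± 83.5 and 361.7 ± 18.6. Bmp6 was at 21.7 ± 5.29, 27.9 ± 5.6 and 30.2 ± 4.91. Values for the unconventional myosin Myo7a (5.21 ± 0.319, 5.08 ± 0.461 and 5.10 ± 0.979) and for the synaptic gene Otof (9.56 ± 1.91, 8.93 ± 3.49 and 10.1 ± 3.63) lay close together. The neuronal tubulin Tubb3 was at 127.9 ± 53.7, 106.3 ± 34.9 and 102.1 ± 83.0. The adenosine receptors Adora1 (3.19 ± 1.09, 2.15 ± 0.795 and 2.45 ± 0.786) and Adora2a (1.88 ± 0.618, 1.37 ± 0.135 and 1.22 ± 0.786), targets of caffeine, did not pass in any comparison. Bmp6 shares 5.7% of its exon bases with Txndc5 and Adora1 20.1% with Mybph, both on the opposite strand.

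The 18 measured genes of the stria vascularis, the epithelium that secretes potassium into the endolymph, were all lower in coffee, with a mean log2 difference of -0.64. Serpinh1 stands in none of the lists, so no list member passed over all 15854 genes in limma. Of the stria genes, 15 had an unadjusted p under 0.05 and 13 passed adjusted over the list alone (limma). The list passed camera at its preset correlation (adjusted p = 1.14e-09), but not with the correlation estimated from the data (adjusted p = 0.618 with an estimated correlation), and the list means of all 4 coffee libraries lay below all 4 controls (exact permutation p = 0.0286). The potassium channel subunits Kcne1 and Kcnq1 were at 16.7 ± 5.18 and 7.40 ± 2.26 FPKM in coffee against 33.0 ± 2.43 and 13.1 ± 1.03 in control (log2 differences -0.99 ± 0.23 and -0.78 ± 0.19). The endocytic receptor Lrp2 (-0.89) and the orphan receptor Esrrb (-0.92), a regulator of strial marginal cells, moved alike. Spiral ligament fibrocyte genes, whose cells recycle potassium, were lower in 11 of 12 members (mean -0.53, 10 passed adjusted over the list alone, camera adjusted p = 4.48e-06, exact permutation p = 0.0286, adjusted p = 0.618 with an estimated correlation). Among them, Slc4a11 was at 113.6 ± 37.6 against 219.1 ± 25.9 (-0.98), Otos at 191.8 ± 72.6 against 347.1 ± 14.9 (-0.92), Coch, which encodes a matrix protein abundant in the inner ear, at 1471 ± 481 against 2316 ± 15.1 (-0.71), and Cp at 50.2 ± 9.004 against 73.3 ± 13.7 (-0.54). Melanocyte genes were lower in 7 of 8 members (mean -0.56), with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.79e-04, exact permutation p = 0.0286, adjusted p = 0.618 with an estimated correlation). Dct (-1.13), Slc45a2 (-0.94), Mlana (-0.93) and Tyr (-0.71), all of pigment synthesis, led that list. Coffee 1, coffee 4 and GTE 1 carried the highest mean log2(FPKM + 1) of the myeloid marrow list, 9.01, 8.60 and 9.07 against 7.36 to 8.44 in the other libraries. Without these 3 libraries the mean difference was -0.33 for the stria list and -0.35 for the fibrocyte list, and with the marrow list as a covariate it was -0.21, -0.26 and, for melanocytes, -0.27.

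Genes of the sensory epithelium were lower in part. Hair cell markers had 18 of 22 members lower (mean -0.24) and 4 passed adjusted over the list alone: the calcium buffer Ocm (21.2 ± 10.3 against 47.6 ± 2.11 FPKM, -1.24), Slc26a5 (-0.74), Tmprss3 (-0.66) and Calb2 (-0.62). The list passed camera at the preset correlation (adjusted p = 3.62e-03; adjusted p = 0.661 with an estimated correlation), had an exact permutation p = 0.143, and did not pass where genes needed a mean FPKM of at least 5. Supporting cell and tectorial membrane genes were lower in 14 of 18 members (mean -0.29; camera adjusted p = 2.60e-03, exact permutation p = 0.0571, adjusted p = 0.645 with an estimated correlation). Of these, 6 passed adjusted over the list alone, among them the tectorial proteins' genes Ceacam16 (-0.73) and Epyc (-0.80), the Notch ligand Jag1 (-0.36) and the connexin Gjb6 (-0.75). Ceacam16 and Epyc share 23.2% and 40.6% of their exon bases with genes on the opposite strand, so their values are uncertain where strand was not used in counting. Cartilage genes were lower in 9 of 9 members (mean -0.37; camera adjusted p = 2.70e-03, exact permutation p = 0.0286, adjusted p = 0.618 with an estimated correlation), and Cnmd (-0.84), Ucma (-0.68), Col9a2 (-0.58) and Col9a3 (-0.44) passed adjusted over the list alone. With the marrow covariate the means were 0.04, -0.08 and -0.17 for hair cells, supporting cells and cartilage, and none of the 3 lists passed. Without the 3 marrow-rich libraries the hair cell mean was -0.08 and the supporting cell mean -0.14. Collagen and matrix genes were lower in 17 of 20 members (mean -0.35; camera adjusted p = 8.15e-05, exact permutation p = 0.0286, adjusted p = 0.618 with an estimated correlation). No member passed adjusted over the list alone in limma, where 9 had an unadjusted p under 0.05, led by Thbs2 (-0.40), Eln (-0.64), Col14a1 (-0.34) and Col6a1 (-0.51). Without coffee 1, coffee 4 and GTE 1 the mean was -0.53.

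Proliferation genes were higher in coffee in all 20 members, with a mean log2 difference of 0.95, and 16 passed adjusted over the list alone (camera adjusted p = 3.42e-08, exact permutation p = 0.0286, adjusted p = 0.627 with an estimated correlation). The mitotic kinase Plk1 was at 13.3 ± 5.36 FPKM against 4.72 ± 1.08 in control (1.27), Ccnb1 at 11.2 ± 4.26 against 4.57 ± 1.54 (1.11), Top2a at 25.4 ± 8.96 against 11.5 ± 4.58 (1.09) and Bub1 at 7.004 ± 2.57 against 3.27 ± 1.34 (0.91). Myeloid marrow genes were higher in all 18 members (mean 0.89; camera adjusted p = 6.2e-07, exact permutation p = 0.0286, adjusted p = 0.618 with an estimated correlation), and 5 passed adjusted over the list alone. They included the granule protein genes Mpo (185.7 ± 60.7 against 57.9 ± 26.9, log2 difference 1.74), Elane (561.1 ± 159 against 197.0 ± 83.7, 1.57), Prtn3 (334.3 ± 95.6 against 116.6 ± 45.8, 1.57) and Ctsg (275.2 ± 59.3 against 106.0 ± 46.5, 1.47). T and NK cell genes were higher in 8 of 8 members (mean 0.68; camera adjusted p = 3.67e-04, exact permutation p = 0.0286, adjusted p = 0.618 with an estimated correlation). Of these Nkg7 (1.44) passed adjusted over the list alone, and Trbc1 (0.60), Cd3d (0.52) and Lck (0.42) did not. Across the 12 libraries the proliferation list followed the myeloid marrow list (Pearson r = 0.93, permutation p = 1e-05, the smallest that the resampling can give; Spearman rho = 0.88, permutation p = 2.4e-04, adjusted p = 5.4e-04). The correlation was 0.85 without the 2 libraries farthest from the median marrow value and 0.94 within groups (3 relations were computed, adjusted p = 3e-05). The stria list ran the opposite way (r = -0.89, permutation p = 2.1e-04, adjusted p = 3.2e-04; rho = -0.88, permutation p = 3.6e-04, adjusted p = 5.4e-04; -0.79 without the 2 farthest libraries and -0.80 within groups). With the marrow covariate the proliferation mean was -0.05 and the T and NK mean 0.14, and neither list passed. Without the 3 libraries richest in marrow transcripts they were 0.52 and 0.32.

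**Figure D1:**
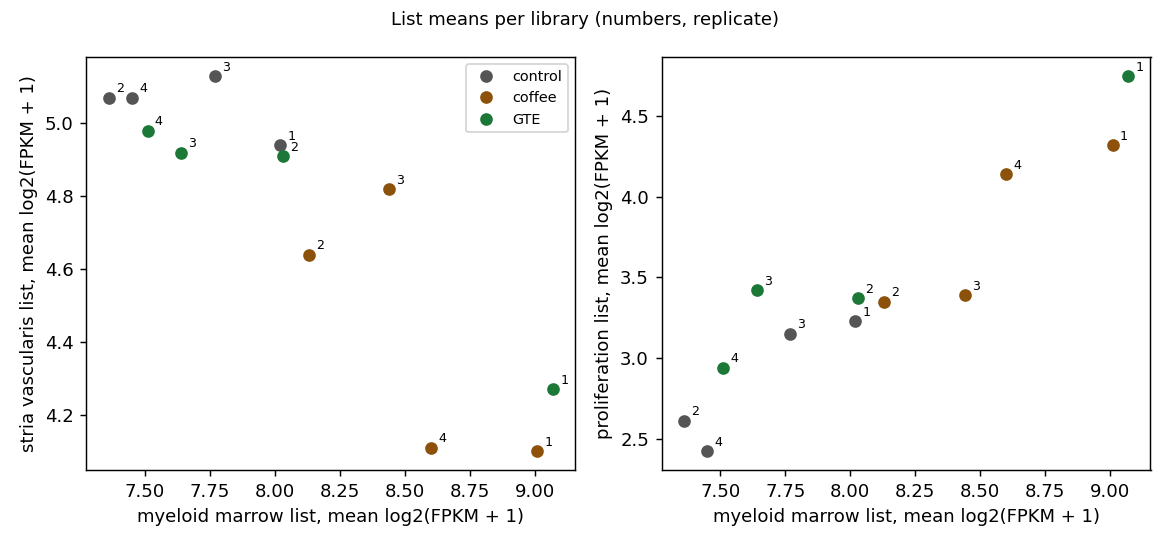
Mean log2(FPKM + 1) of the myeloid marrow list (x axis) against the mean of the stria vascularis list (left panel, y axis) and of the proliferation list (right panel, y axis), 1 point per library, coloured by group and numbered by replicate. Coffee 1, coffee 4 and GTE 1, with marrow values of 9.01, 8.60 and 9.07, have the 3 lowest stria values (4.10, 4.11 and 4.27) and the 3 highest proliferation values (4.32, 4.14 and 4.75).

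Interferon response genes were higher in coffee in all 18 members, with a mean of 0.88 (camera adjusted p = 3.36e-05, exact permutation p = 0.143, adjusted p = 0.645 with an estimated correlation). No member passed adjusted over the list alone in limma, where 5 had an unadjusted p under 0.05. Oas1a was at 33.3 ± 27.8 FPKM against 10.2 ± 2.07 in control (1.31), Ifi27l2a at 383.3 ± 170 against 215.4 ± 42.0 (0.76) and Oasl2 at 36.8 ± 31.7 against 13.4 ± 1.76 (1.06). The list mean was 6.20 in coffee 1 and 3.84 to 4.85 in the other coffee libraries, against 3.51 to 4.32 in control, and the difference was 0.41 without coffee 1, 0.57 with the marrow covariate and 0.44 without the 3 marrow-rich libraries. Oas1a belongs to a family of close copies, so its value is uncertain. Targets of the aryl hydrocarbon receptor, a sensor of plant compounds and combustion products, were lower in 5 of 6 members (mean -0.30; camera adjusted p = 0.0120, exact permutation p = 0.0571, adjusted p = 0.618 with an estimated correlation). Cyp1b1 (24.9 ± 2.88 FPKM against 37.5 ± 3.78, -0.57) and Nqo1 (10.7 ± 0.916 against 13.9 ± 1.98, -0.35) passed adjusted over the list alone, while Tiparp (-0.28) and Aldh3a1 (-0.31) did not. Without control 3 the list mean was -0.21 and the call was lost, and with no filter on low values it was -0.20. Cyp1a1, another target, had at most 0.822 FPKM in any library and was not tested (0.477 ± 0.285 in control, 0.302 ± 0.247 in coffee and 0.226 ± 0.138 in GTE).

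**Figure D2:**
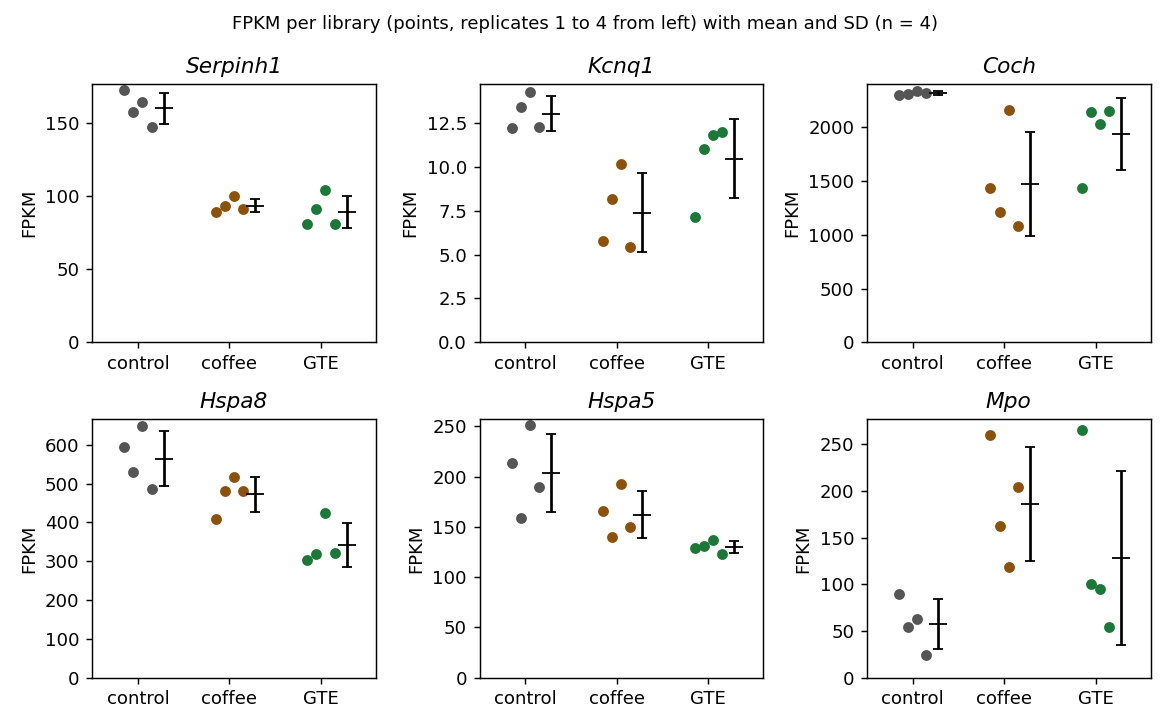
FPKM (y axes, from 0) of Serpinh1, Kcnq1, Coch, Hspa8, Hspa5 and Mpo in the control, coffee and GTE groups (x axes), 1 point per library, with the mean and SD of 4 libraries as bars. Serpinh1 lies near 160.1 FPKM in control and near 93.5 and 89.2 FPKM in coffee and GTE, with no overlap with control.

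The comparison of GTE with control asked which cochlear transcripts differed after long-term intake of green tea extract. Heat shock and unfolded protein response genes, which encode chaperones of the cytosol and of the endoplasmic reticulum, were lower in GTE in 19 of 21 members, with a mean log2 difference of -0.55 (adjusted p = 0.365 with an estimated correlation). Serpinh1 fell by 0.84 ± 0.09 (SE), to 89.2 ± 10.7 FPKM (adjusted p = 0.0190; lower in 4 of 4 libraries than in any control, exact permutation p = 0.0286), and was the only gene that passed over all 15854 genes in limma. Mean values of the lists of red cell precursors, of B lineage cells and of dividing cells were higher by 1.05, 0.58 and 0.77. These 3 list calls did not hold beyond the preset correlation of camera (adjusted p = 0.657 with an estimated correlation for each), and no member passed in limma even over the list alone. At an unadjusted p under 0.05 stood 1337 genes, of which 656 were higher and 681 lower, or 49.1% higher, against 38.7% after quantile normalization and 61.9% with the marrow covariate. The Serpinh1 call was lost without any of 9 libraries, with adjusted p of 0.131, 0.108, 0.135 and 0.0514 without controls 1 to 4, 0.0614 without coffee 2 and again without coffee 4, and 0.0685, 0.109 and 0.107 without GTE 1, 2 and 4. Serpinh1 passed in 15 of 28 alternatives, with a log2 difference from -0.92 to -0.80 and an adjusted p from 7.79e-03 to 0.178. The call was also lost with the replicate block (adjusted p = 0.0573), with only the 8 libraries compared (0.178), with the marrow covariate (0.0570) and without the 3 libraries richest in marrow transcripts (0.138).

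The other genes with the smallest p-values did not pass (adjusted p from 0.280 to 0.408). Depp1, a target of FOXO factors, was at 1.96 ± 0.531 FPKM in GTE against 6.07 ± 1.37 in control (log2 difference -1.25 ± 0.20 SE). Ace, the angiotensin-converting enzyme, was at 2.73 ± 0.281 against 4.80 ± 0.114 (-0.64 ± 0.10), with Tspan11 (-0.77) and Spsb1 (-0.52) also on the lower side. On the higher side were Gas2l3 (0.52), the exonuclease Exo5 (0.42), the TGF-beta family ligand Lefty1 (0.39) and the antibody joining segments Ighj2 (1.37) and Igkj3 (1.94). The last pair are segments of 100 and 38 bases in loci of near-identical copies, so their values are uncertain, and Ace shares 5.6% of its exon bases with a gene on the opposite strand.

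Of the heat shock and unfolded protein response list, 14 of 21 members were lower adjusted over the list alone. The list passed camera at the preset correlation (adjusted p = 4.18e-14) and fry (adjusted p = 0.0489), but not with an estimated correlation (adjusted p = 0.365 with an estimated correlation), and all 4 GTE libraries had lower list means than any control (exact permutation p = 0.0286). Hspa8, the constitutive HSP70 of the cytosol (ENSMUSG00000015656), was at 341.9 ± 55.9 FPKM in GTE against 564.3 ± 71.0 in control (-0.73 ± 0.13), and Hspa5, the endoplasmic reticulum chaperone BiP, at 129.9 ± 5.95 against 203.7 ± 38.8 (-0.63 ± 0.14). Manf (14.6 ± 0.946 against 21.8 ± 3.35, -0.54) and Creld2 (30.2 ± 1.84 against 46.4 ± 7.92, -0.59), secreted products of endoplasmic reticulum stress, moved alike. Pituitary genes, listed after the data were seen, had a mean of -2.39 in the same comparison (exact permutation p = 0.0286). In coffee these 4 chaperone genes lay between both other groups, at 471.9 ± 45.5, 162.1 ± 22.9, 19.0 ± 2.21 and 38.8 ± 5.33 FPKM. Collagen and matrix genes were lower in 19 of 20 members (mean -0.27; camera adjusted p = 1.01e-04, exact permutation p = 0.0571, adjusted p = 0.657 with an estimated correlation). Elastin, Eln, passed adjusted over the list alone at 2.05 ± 0.124 against 5.55 ± 2.41 (-1.03), and Col6a3 (-0.40), Col14a1 (-0.33) and Col6a2 (-0.45) did not. Circadian clock genes did not pass as a list (mean -0.08, limma camera adjusted p = 0.0669, exact permutation p = 0.400), yet 2 members were higher and 3 lower adjusted over the list alone. They included Cry1 (-0.32), Arntl (-0.62) and Nfil3 (-0.83) on the lower side and Nr1d1 (0.70), a repressor of Arntl, on the higher side. Nr1d1 shares 8.5% of its exon bases with Thra on the opposite strand.

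Erythroid genes were higher in GTE in all 17 members (mean 1.05; camera adjusted p = 2.98e-06, exact permutation p = 0.0857, adjusted p = 0.657 with an estimated correlation). No member passed adjusted over the list alone in limma, where Car1 (22.4 ± 18.5 FPKM against 5.62 ± 3.60, 1.72) and the spectrin Sptb (0.47) were the 2 with an unadjusted p under 0.05, which Ermap (1.43) did not have. B lineage genes were higher in 13 of 14 members (mean 0.58; camera adjusted p = 1.09e-04, exact permutation p = 0.0857, adjusted p = 0.657 with an estimated correlation). In limma 4 of them had an unadjusted p under 0.05 and none passed adjusted over the list alone, with Cd79b (1.00), Rag1 (0.60) and Cd79a (0.93) in front. Proliferation genes were higher in all 20 members (mean 0.77; camera adjusted p = 1.5e-08, exact permutation p = 0.143, adjusted p = 0.657 with an estimated correlation), with Ccnb1 (0.96) and Cenpf (0.66) at an unadjusted p under 0.05 ahead of Birc5 (0.88) and Bub1 (0.74). GTE 1, the library with the highest myeloid marrow value, also had the highest erythroid (6.29), B lineage (3.83) and proliferation (4.75) list means of all libraries. Without it the mean differences were 0.67 for erythroid, 0.37 for B lineage and 0.39 for proliferation genes, and with the marrow covariate 0.53, 0.37 and 0.31.

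Stria vascularis genes were lower in GTE in 17 of 18 members (mean -0.28; camera adjusted p = 1.01e-04, exact permutation p = 0.0571, adjusted p = 0.673 with an estimated correlation). Among them Wnk4 (-0.32) had an unadjusted p under 0.05 in limma, and Esrrb (-0.49) did not. The mean was -0.11 without GTE 1 and -0.09 with the marrow covariate. Endothelial genes were lower in 11 of 11 members (mean -0.19; camera adjusted p = 1.01e-04, exact permutation p = 0.0857, adjusted p = 0.657 with an estimated correlation). Pecam1 (-0.26), Eng (-0.20) and Tek (-0.19) had an unadjusted p under 0.05, and Flt1 (-0.32) did not. Immediate early genes were lower in 18 of 19 members (mean -0.31; camera adjusted p = 1.36e-03, exact permutation p = 0.286, adjusted p = 0.657 with an estimated correlation), with Jun (-0.38), Klf2 (-0.50), Dusp1 (-0.52) and Egr3 (-0.69) in front. Control 1 had the highest mean of that list (4.64), and without it the difference was -0.12 and the call was lost. Airway and middle ear epithelium genes were lower in 10 of 12 members (mean -0.78; camera adjusted p = 1.43e-03, exact permutation p = 0.286, adjusted p = 0.657 with an estimated correlation), among them the genes of motile cilia Foxj1 (-1.11), Dnah5 (-0.67) and Dynlrb2 (-0.95) and the cadherin Cdhr3 (-0.96). That call was lost without control 3 (mean -0.40) and without GTE 3 (-0.42), and the mean was -1.22 with voom.

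**Figure D3:**
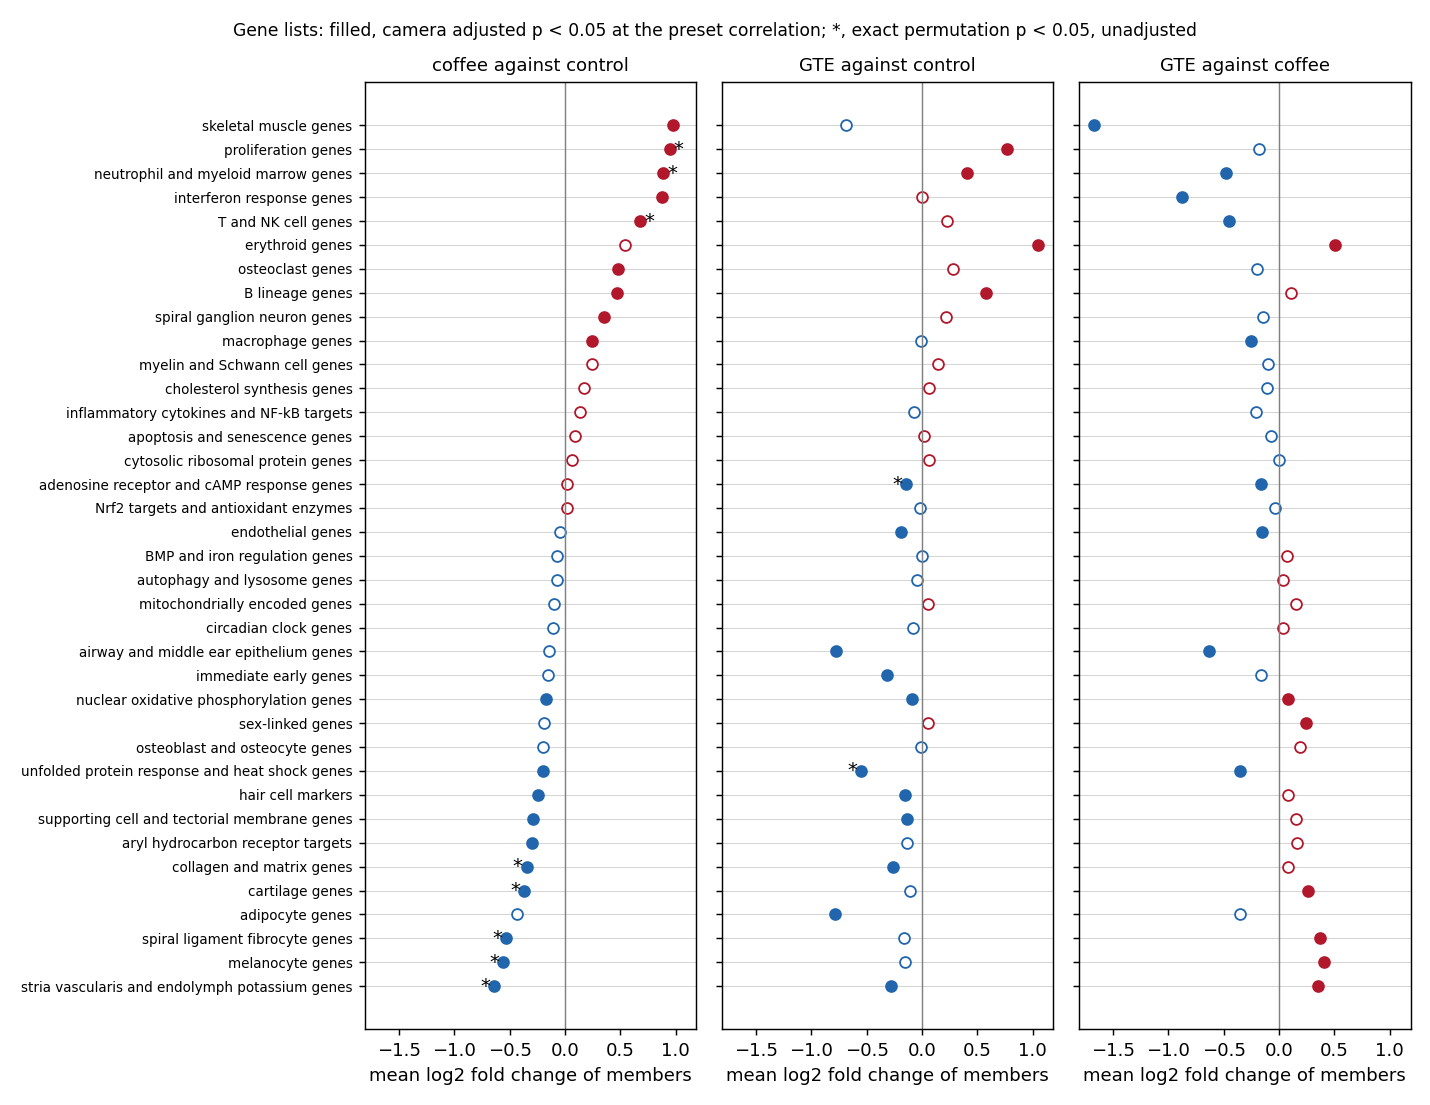
Mean log2 fold change of the tested members (x axes) of the 37 gene lists (1 line per list on the y axes) for coffee against control, GTE against control and GTE against coffee. Filled points passed camera at its preset correlation, open points did not, and a star marks an exact permutation p of the list means under 0.05 before adjustment; the stria list has -0.64 in the first panel and the heat shock list -0.55 in the second.

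GTE against coffee tested the difference between the effects of both drinks, since the control cancels. Mean values of the interferon, skeletal muscle and chaperone lists were lower in GTE than in coffee, whereas those of the fibrocyte, melanocyte and stria lists were higher. These 6 list calls did not hold beyond the preset correlation of camera (adjusted p from 0.502 to 0.555 with an estimated correlation). Their exact permutation p ran from 0.0571 to 0.171. No gene passed over all 15854 in limma (smallest adjusted p = 0.126, Ace), with 1071 at an unadjusted p under 0.05, 717 of them higher and 354 lower in GTE, and limma voom on the recovered fragments gave 0 as well. The share of higher genes, 66.9%, was 45.2% without coffee 1 and 44% with the marrow covariate. Ace was at 2.73 ± 0.281 FPKM in GTE and 5.59 ± 1.04 in coffee (log2 difference -0.81 ± 0.10 SE). Complement C4b (-0.57), Ap1s2 (-0.39), Cry1 (-0.34) and Bcl6 (-0.25) followed on the lower side, and the hyaluronidase Cemip (0.48), the pyruvate dehydrogenase kinase Pdk1 (0.46), Cryl1 (0.44), Pskh1 (0.37) and Dtd2 (0.33) stood on the higher side. C4b has a near-identical neighbouring copy, so its value is uncertain. Without coffee 2 the limma count was 1, the antibody segment Ighv1-22 (-1.97, adjusted p = 0.0275), named here after its value was seen. The 1071 became 3232 without GTE 1, 1769 without coffee 3, 669 without coffee 4 and 590 without GTE 2.

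Interferon response genes were lower in GTE than in coffee in all 18 members (mean -0.88; camera adjusted p = 8.56e-09, exact permutation p = 0.171, adjusted p = 0.502 with an estimated correlation), with Ifi27l2a (-0.99), Oas1a (-1.27), Usp18 (-1.18) and Irf7 (-1.32) in front, and the mean was -0.41 without coffee 1 and -0.39 without the 3 marrow-rich libraries. Skeletal muscle genes were lower in 15 of 15 members (mean -1.67; camera adjusted p = 7.31e-07, exact permutation p = 0.143, adjusted p = 0.502 with an estimated correlation). Coffee 3 had the highest muscle list mean (6.11, against 1.17 to 4.56 in the other libraries), and without it the mean difference was -0.85. Mybpc1 (-0.77), Myh1 (-1.60), Pygm (-0.79) and Atp2a1 (-2.25) led that list; Myh1 has close copies, and 21.9% of the exon bases of Atp2a1 lie under Rabep2 on the opposite strand. Chaperone genes were lower in 19 of 21 members (mean -0.35; camera adjusted p = 7.31e-07, exact permutation p = 0.0571, adjusted p = 0.502 with an estimated correlation), with Hspa8 (-0.47), Manf (-0.35), Hsph1 (-0.75) and Creld2 (-0.34) among the 8 at an unadjusted p under 0.05 in limma, none of which passed adjusted over the list alone. Macrophage genes were lower in 12 of 14 members (mean -0.25; camera adjusted p = 1.03e-03, exact permutation p = 0.229, adjusted p = 0.544 with an estimated correlation), led by C1qa (-0.30), C1qb (-0.31), Lyz2 (-0.63) and C1qc (-0.26). Without coffee 1 that mean was -0.17, and the call was lost without the 3 marrow-rich libraries (-0.10) and with the marrow covariate (-0.08).

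Fibrocyte genes were higher in GTE than in coffee in 9 of 12 members (mean 0.37; camera adjusted p = 2.89e-05, exact permutation p = 0.0857, adjusted p = 0.502 with an estimated correlation). Slc4a11 (0.82), Otos (0.83), Pou3f4 (0.57) and Car3 (0.76) passed adjusted over the list alone. Melanocyte genes were higher in 8 of 8 members (mean 0.41; camera adjusted p = 3.29e-04, exact permutation p = 0.0857, adjusted p = 0.502 with an estimated correlation), of which Dct (0.79), Slc45a2 (0.67) and Mlana (0.72) passed adjusted over the list alone and Tyr (0.57) did not. Stria genes were higher in 17 of 18 members (mean 0.36; camera adjusted p = 6.51e-06, exact permutation p = 0.171, adjusted p = 0.555 with an estimated correlation). No stria member passed adjusted over the list alone in limma, where 6 had an unadjusted p under 0.05, led by Slc26a4 (0.88), Kcne1 (0.61), Car12 (0.59) and Kcnq1 (0.46). With the marrow covariate the means were 0.22, 0.25 and 0.13, and the stria call was lost. Without the 3 marrow-rich libraries the stria mean was 0.21.

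Both treatments were also set side by side, because they share the control libraries. Log2 differences from control correlated across the 15854 genes with r = 0.678, where genes are not independent replicates. Unchanged groups simulated against the same controls gave a mean of 0.424 in 100 simulations. The simulated interval, which leaves out the extremes, ran from -0.508 to 0.896. The covariance was 0.0627 against a mean of 0.0233 in the simulations, a difference of 0.0394. It lay inside the simulated interval of -0.0224 to 0.085. With the controls split into separate pairs r was 0.276 to 0.447. At an unadjusted p under 0.05, 321 genes were higher in both treatments and 319 lower. Simulation gave means of 73.2 and 61.9, with upper interval ends of 425 and 507 that are not maxima. Independent lists would share 60.7 and 73.4. Without GTE 1 the correlation was 0.426. In the test of any difference between the 3 groups Serpinh1 alone passed in limma (adjusted p = 0.0277; 1998 genes at an unadjusted p under 0.05), and that call was lost without any 1 of the controls, coffee 1, coffee 2, coffee 4, GTE 2 or GTE 4. Without coffee 2 the gene that passed was Ighv1-22, without coffee 3 there were 15 genes, and without GTE 1 there were 5, namely Serpinh1, Tspan11, Aldh1a3, Igfbp5 and Htra3, the last 3 named after their values were seen.

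The remaining lists were weaker or rested on few libraries, and are given with the libraries and settings that ended a call or moved a mean most. In coffee against control, spiral ganglion neuron genes had a mean of 0.36 (limma camera adjusted p = 0.0201, adjusted p = 0.727 with an estimated correlation). The call was lost without coffee 2 (0.20), without control 3 (0.17) and with a mean FPKM of at least 5 (0.35). The mean was 0.55 without control 2 and 0.87 with the marrow covariate. Nociceptor genes, of neurons in other ganglia and listed after the data were seen, had 1.09 (exact permutation p = 0.314). Control 2 and coffee 2 had the highest means of these 8 libraries in both lists (4.79 and 5.02 for ganglion neurons, 3.87 and 3.72 for nociceptors). Osteoclast genes had 0.48 (8.31e-03, adjusted p = 0.645 with an estimated correlation, lost without coffee 1, 0.33, and with the covariate, -0.09). B lineage genes had 0.47 (0.0128, adjusted p = 0.661 with an estimated correlation, lost without coffee 4, 0.28, and with the covariate, 0.03). Without the 3 marrow-rich libraries these 2 means were 0.22 and 0.16, and neither list passed. Macrophage genes had 0.24 (0.0438, adjusted p = 0.661 with an estimated correlation) and passed in 14 of 24 alternatives. They lost the call without coffee 1 (0.16), coffee 4 (0.17), control 2 (0.20), control 3 (0.24) or GTE 1 (0.24), with the covariate (-0.07) and without the 3 marrow-rich libraries (0.01). A pseudocount of 0.1 (0.25), FPKM rescaled without marrow and muscle lists (0.28) and voom (0.25) ended it as well. Skeletal muscle genes had 0.98 (0.0276, adjusted p = 0.727 with an estimated correlation) and passed in 17 of 24. Losses came without coffee 3 (0.16), control 2 (0.53), control 4 (0.68) or GTE 1 (0.98) and with the covariate (0.37), with a mean FPKM of at least 5 (1.03) and with FPKM rescaled without marrow and muscle lists (1.004). The mean was 1.61 without control 3 and 1.52 without the 3 marrow-rich libraries. Nuclear oxidative phosphorylation genes had -0.17 (2.04e-04, adjusted p = 0.661 with an estimated correlation, -0.08 without coffee 1, -0.26 without coffee 3). The call was lost with the covariate (0.04) and without the 3 marrow-rich libraries (-0.04). Chaperone genes had -0.20 (4.4e-03, adjusted p = 0.645 with an estimated correlation, lost without control 3, -0.08), and -0.08 both with the covariate and without the 3 marrow-rich libraries.

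In GTE against control, adipocyte genes had -0.78 (limma camera adjusted p = 1.36e-03, adjusted p = 0.657 with an estimated correlation, lost without GTE 2, -0.43; -0.36 with the covariate). Hair cell markers had -0.16 (0.0171, adjusted p = 0.728 with an estimated correlation, lost without GTE 1, -0.01, control 1, -0.12, or control 2, -0.08, with the covariate, -0.03, and with a mean FPKM of at least 5, -0.11). Supporting cell genes had -0.14 (0.0420, adjusted p = 0.728 with an estimated correlation) and passed in 15 of 24 alternatives. Among their losses were the fits without GTE 1 (-0.03), GTE 4 (-0.14), control 1 (-0.12), control 2 (-0.115) or control 3 (-0.13) and with the covariate (-0.04), a mean FPKM of at least 5 (-0.15) or quantile normalization (-0.15). The mean was -0.22 without GTE 2. Oxidative phosphorylation genes had -0.09 (0.0130, adjusted p = 0.797 with an estimated correlation, lost without GTE 1, -0.03, control 2, -0.04, or control 4, -0.08, with quantile normalization, -0.08, and with the covariate, 0.005). Myeloid marrow genes had 0.41 (6.08e-03, adjusted p = 0.728 with an estimated correlation, lost without GTE 1, 0.08, or control 2, 0.31). Without the 3 marrow-rich libraries, of which only GTE 1 stands in this comparison, the hair cell, supporting cell, oxidative phosphorylation and myeloid marrow means were -0.01, -0.03, -0.03 and 0.08, and none of these 4 lists passed. Adenosine and cAMP response genes had -0.14 (0.0478, adjusted p = 0.657 with an estimated correlation, exact permutation p = 0.0286) and passed in 12 of 24 alternatives. The list did not pass without control 1 (-0.09), control 4 (-0.15), coffee 1 (-0.14), GTE 2 (-0.13), GTE 3 (-0.15) or GTE 4 (-0.14) and with the covariate (-0.13). Further losses came with a mean FPKM of at least 5 (-0.17), median-of-ratios scaling (-0.145), FPKM rescaled to the same sum (-0.15) and the replicate block (-0.14), and without the 3 marrow-rich libraries (-0.15).

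In GTE against coffee, myeloid marrow genes were at -0.48 (limma camera adjusted p = 4.44e-05, adjusted p = 0.567 with an estimated correlation, -0.82 without GTE 1, -0.30 without GTE 4). T and NK genes were at -0.45 (3.04e-04, adjusted p = 0.502 with an estimated correlation, -0.28 without coffee 1, -0.30 without GTE 4, lost with the covariate, -0.16). Endothelial genes were at -0.15 (1.43e-03, adjusted p = 0.502 with an estimated correlation). Airway genes were at -0.64 (4.86e-03, adjusted p = 0.567 with an estimated correlation, lost without GTE 3, -0.28, or coffee 3, -0.50, and with a mean FPKM of at least 5, -0.76). Their mean was -1.055 with voom and -1.03 without the 3 marrow-rich libraries. Adenosine response genes were at -0.17 (0.0334, adjusted p = 0.544 with an estimated correlation, lost without coffee 2, -0.07, or GTE 1, -0.17, with the replicate block, -0.17, and with a mean FPKM of at least 5, -0.11). Erythroid genes were at 0.51 (4.98e-03, adjusted p = 0.728 with an estimated correlation, lost without GTE 1, 0.13, coffee 2, 0.33, or coffee 3, 0.07). The mean was 0.77 without coffee 1, 0.87 without coffee 4 and 1.12 with the covariate. Cartilage genes were at 0.26 (3.19e-03, adjusted p = 0.502 with an estimated correlation, lost with the covariate, 0.16). Sex-linked genes were at 0.25 (2.77e-03, adjusted p = 0.502 with an estimated correlation, 0.135 without coffee 4). The call was lost with the covariate (0.20) and without the 3 marrow-rich libraries (0.14). Oxidative phosphorylation genes were at 0.08 (0.0288, adjusted p = 0.728 with an estimated correlation) and passed in 16 of 24 alternatives. They did not pass without coffee 1 (-0.01), coffee 2 (0.08), GTE 3 (0.05) or GTE 4 (0.05) and with the covariate (-0.03), nor with a mean FPKM of at least 5 (0.08), quantile normalization (0.08) or without the 3 marrow-rich libraries (0.01). The mean was 0.17 without coffee 3 and 0.14 without GTE 1.

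Of the 19, 15 and 16 list calls in the 3 comparisons none held with an estimated correlation (smallest adjusted p = 0.618, 0.365 and 0.502). That setting found a list shifted by -0.5 in 0% of simulations with libraries varying together, so this loss does not tell real calls from false ones. Exact permutation p-values adjusted over the 37 lists were at least 0.132, 0.453 and 0.453. Myelin, osteoblast, Nrf2 and antioxidant, inflammatory, BMP and iron, apoptosis, autophagy, cholesterol synthesis, ribosomal protein and mitochondrially encoded genes passed in no comparison, with means in coffee of 0.24, -0.20, 0.02, 0.13, -0.08, 0.09, -0.08, 0.18, 0.06 and -0.10, and in GTE of 0.14, -0.01, -0.02, -0.07, 0.00, 0.02, -0.04, 0.06, 0.06 and 0.05. The mean and the median differed in sign for Nrf2 genes in coffee (0.02 and -0.04) and for macrophage (-0.01 and 0.02) and mitochondrially encoded genes in GTE, while camera pointed down for adenosine response genes in coffee (mean 0.02) and for interferon (0.00) and apoptosis genes in GTE.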

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

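Among the tests in this part, those of an even dilution of the inner ear for the stria list and of leaving out coffee 1 for the interferon list were chosen only after the result was seen. A library was picked out where it stood apart from the other 3 of its group by Dixon's gap criterion at its 95% level. Looked at were 134 reported genes, 37 lists and 2 measures of the libraries (FPKM denominator and number of genes above 0). Of the 519 groups, 31 had such a library, and since chance flags about 1 in 20 groups, 26 would be due to chance alone.

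GTE 1 stood apart in 11 of these. FPKM was high there for Birc5 (25.1 against 6.50 to 8.51 in the other GTE libraries), Ccnb1 (21.6 against 5.77 to 8.33) and Top2a (45.5 against 11.8 to 16.7). It was low there for Coch (1442 against 2035 to 2146), Col9a3 (11.4 against 16.9 to 17.1), Jag1 (5.02 against 6.62 to 6.76), Kcne1 (15.4 against 29.2 to 29.9) and Slc45a2 (11.8 against 16.8 to 17.4). The mean log2(FPKM + 1) of the stria list was 4.27 against 4.91 to 4.98, that of the cartilage list 3.77 against 4.13 to 4.19, and that of the immediate early list 4.17 against 3.62 to 3.63. The other GTE libraries that stood apart were GTE 2 for C1qb (92.3 FPKM against 74.4 to 76.6) and the interferon list (4.62 against 3.59 to 3.73), and GTE 3 for Hspa8 (425 FPKM against 303 to 321).

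Coffee 3 was high for the muscle genes Atp2a1 (112 FPKM against 2.08 to 7.73) and Myh1 (25.4 against 0.606 to 3.92) and for the fibrocyte genes Otos (300 against 143 to 163) and Pou3f4 (35.1 against 22.7 to 24.5), and low for Thbs2 (4.18 against 5.31 to 5.50). Coffee 1 was high for Ctsg (364 FPKM against 237 to 251) and Trbc1 (5.10 against 2.33 to 2.46) and low for Ahr (2.58 against 2.78 to 2.81). Control 3 was high for Ahr (7.85 FPKM against 2.45 to 2.90) and for the cilia genes Dynlrb2 (32.5 against 13.9 to 15.8) and Foxj1 (31.4 against 11.2 to 14.4). Control 2 was high for Adora2a (2.39 FPKM against 0.684 to 0.948) and Otos (369 against 338 to 342) and low in the mean of the T and NK list (1.44 against 1.73 to 1.79). Control 1 was high in the B lineage list (3.00 against 2.51 to 2.52) and the clock list (3.52 against 3.30 to 3.33), and control 4 in the mitochondrially encoded list (9.51 against 8.92 to 8.94).

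The first pattern weighed is the lower stria list in coffee (mean log2 difference -0.64, SE 0.21). An even dilution of the inner ear would lower the hair cell, supporting cell, ganglion neuron and myelin lists alike. The stria list fell below the mean of these 4 by -0.65 in coffee (exact permutation p = 0.0286, lower in 4 of 4 libraries). The 4 lists moved apart (-0.24, -0.29, 0.36 and 0.24, a mean of 0.02 with an exact permutation p = 0.857). Their own exact permutation p-values were 0.143, 0.0571, 0.286 and 0.314. Because their mean joins lists of opposite sign, the test cannot decide on a dilution. A share of bone marrow RNA that differs between dissections is a candidate source: with the myeloid marrow list as a covariate the stria difference was -0.21 (SE 0.17; limma camera adjusted p = 2.81e-03). The 18 tested marrow genes were also measured in control cochleae, and their most abundant members were S100a9 (7427 ± 1706 FPKM in control, 11620 ± 2368 in coffee and 9800 ± 4470 in GTE) and S100a8 (2617 ± 559, 4157 ± 782 and 3197 ± 1397). An effect of coffee on the stria, or on marrow and stria together, stays open and was not tested apart from it.

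The second pattern is the lower chaperone list in GTE (-0.55, SE 0.14), where a list of pituitary genes, drawn up after the data were seen, was lower too (-2.39, exact permutation p = 0.0286). Marrow RNA is argued against, since with the marrow covariate the difference was -0.49 (SE 0.15; limma camera adjusted p = 5.77e-16). A lower glucocorticoid response at collection is a candidate explanation. A list of 15 glucocorticoid response genes, drawn up after the data were seen, was lower in GTE by -0.48 (exact permutation p = 0.0286, lower in 4 of 4 libraries than in any control). In coffee it was lower too, by -0.32 (exact permutation p = 0.0857), where the chaperone list was at -0.20. Its member Mt2 had at most 0.0731 FPKM in any library, but shares 73.5% of its exon bases with a gene on the opposite strand. The value of Mt2 is thus uncertain. Lcn2, another member, had a higher mean in GTE (384 ± 263 FPKM against 306 ± 108 in control). It was at 761.7 FPKM in GTE 1 and at 192.2 to 364.7 in the other GTE libraries. Across the 12 libraries the glucocorticoid list followed the chaperone list (r = 0.69, permutation p = 0.012, adjusted p = 0.012, and rho = 0.85, permutation and adjusted p = 1.1e-03). That r was 0.90 without the 2 libraries farthest from the median, but 0.20 within groups. The time of day at collection cannot be told apart with these samples, because the evening minus morning arm of the clock differed by 0.77 in GTE with an exact permutation p = 0.0857 (0.62 in coffee, p = 0.143). A direct effect of the extract on protein folding and a share of pituitary RNA also stay open and were not tested.

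The third pattern is the higher interferon list in coffee (0.88, SE 0.49). A response in the tissue of a single library may account for part of it. Without coffee 1 the difference was 0.41 (SE 0.35, limma camera adjusted p = 2.89e-03). Coffee 1 held the highest list mean (6.20), so leaving it out had to lower the difference. Coffee 2 (4.85) also lay above every control (3.51 to 4.32). Marrow RNA cannot be told apart from other sources, because with the covariate the difference was 0.57 with an SE of 0.67 (limma camera adjusted p = 0.0310), wider than the change it would have to show. A smaller effect of coffee shared by the remaining libraries stays open and was not tested.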

How the results depend on the processing

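The fits on recovered fragments with voom and without the 3 libraries richest in marrow transcripts, and the exact tests of list means, were chosen only after the data were seen. With a pseudocount of 0.1 or 0.5, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization or voom, the gene counts were 1 for coffee against control, 1 for GTE against control, 0 for GTE against coffee and 1 for any group, and that gene was Serpinh1. Counts in that order were 0, 1, 0 and 0 with no filter beyond FPKM above 0 in at least 1 library, with FPKM rescaled to the same sum, and with FPKM rescaled to the same sum without marrow and muscle lists. They were 0, 1, 0 and 1 with eBayes without trend and with robust eBayes. With only the 8 libraries compared they were 0, 0 and 0, and with the marrow covariate, or leaving out the 3 libraries richest in marrow transcripts, 0, 0, 0 and 0. With arrayWeights they were 2437, 4, 365 and 700. The 4 were Serpinh1, Tspan11, Depp1 and Gm10736, the last named after its values were seen. These weights ran from 0.213 for GTE 1 to 2.255 for control 1 and were estimated from the same spread that the test uses. Other splits of the 8 libraries reached 1517 weighted genes for coffee, 464 for GTE and 5099 for GTE against coffee.

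With 1 library left out, the gene counts ran from 0 to 98 for coffee, from 0 to 1 for GTE and for GTE against coffee, and from 0 to 15 for any group. List counts, 19, 15 and 16 in the 3 comparisons, ran from 17 to 22, 13 to 18 and 15 to 23. The correlation of both treatments' fold changes, 0.678, ran from 0.426 to 0.736 and was 0.329 without the 3 libraries richest in marrow transcripts. With the estimated correlation 0, 0 and 0 lists passed, with fry 0, 1 and 0, and with the exact permutation test of list means, adjusted, 0, 0 and 0. In the exact test only 8, 2 and 0 lists had a p under 0.05 before adjustment, so most list calls ended there without it. For the lists at the smallest p, 70 arrangements cannot give a p small enough for 37 lists unless many reach it. For the other changes the cause was not tested.

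The sign turned for 8 values of list means. With the marrow covariate these were hair cell (0.038), osteoclast (-0.086), macrophage (-0.073), proliferation (-0.05) and nuclear oxidative phosphorylation genes (0.037) in coffee against control, and nuclear oxidative phosphorylation genes in GTE against control (0.005) and GTE against coffee (-0.032). In GTE against coffee that list was also at -0.014 without coffee 1, within a range of -0.014 to 0.167 over the 12 libraries left out. The cause was not tested. Of the planned values of single genes, 4423 kept their direction and their side of the threshold, 97 came to pass, 29 no longer passed, and 39 that passed in neither fit changed sign. Of the planned list values, 1007 kept both and 179 kept the direction but no longer passed.

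The replicate numbers did not clearly pair the libraries, though a pairing is not excluded. Across 12 pairs with the same number the correlation of deviations from the group means ran from -0.383 to 0.55, with 5 pairs over 0.1. Their mean was 0.07, against -0.024 for pairs with other numbers, and 4 of the 12 libraries correlated best with their own number. With the replicate number as a block the gene counts were 0, 0, 0 and 0. Genes at an unadjusted p under 0.05 in limma were then 3978, 1866 and 1385, against 3175, 1337 and 1071 without the block. At 20526024 to 24835934 fragments per library, depth limits genes near 0.060 to 0.073 FPKM, below the 1 FPKM asked for.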

Other observations

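The tests of lists outside the 37 fixed ones were chosen only after the data were seen. Besides the clock list, 3 lists that did not pass in GTE against control held single genes that passed adjusted over the list alone in limma, though not over all 15854 genes. Of the Nrf2 and antioxidant list (mean -0.02), Sod3, the extracellular superoxide dismutase, was at 8.88 ± 1.97 FPKM in GTE, 16.2 ± 3.92 in coffee and 18.0 ± 3.72 in control (log2 difference -0.95 ± 0.20 SE, adjusted p = 0.0144 over the list alone), while Gpx3 (-0.46), Gclm (0.32) and Gsta3 (-0.37) did not pass. Of the apoptosis and senescence list (mean 0.02), the cell cycle inhibitor Cdkn1a was at 30.5 ± 3.43 in GTE, 31.8 ± 3.2 in coffee and 50.7 ± 9.82 in control (-0.70 ± 0.14, adjusted p = 5.63e-03 over the list alone), while Bcl2l1 (-0.23) and Bax (-0.18) did not pass. Of the aryl hydrocarbon receptor targets (mean -0.14), Cyp1b1 was at 27.7 ± 3.65 in GTE against 37.5 ± 3.78 (-0.43 ± 0.11, adjusted p = 0.0193 over the list alone), while Aldh3a1 (-0.25), Nfe2l2 (-0.04) and Ahr (-0.09) did not pass. Such genes were not particular to GTE: in coffee against control, Gsta4 (-0.98), Gpx3 (-0.58) and Gclm (0.44) of the Nrf2 list, Cdkn1a (-0.64) and Emcn (-0.61) of the endothelial list passed adjusted over the list alone, as did Calb2 (0.75) of the hair cell list and Cry1 (-0.34) in GTE against coffee. These were named after their values were seen.

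Transcripts of tissues near the cochlea varied widely between libraries. Pituitary genes had a mean log2 difference of -2.39 in GTE against control (exact permutation p = 0.0286) and -1.34 in coffee (exact permutation p = 0.314). Growth hormone, Gh, ran from 1577 FPKM in control 1 to 1.99 in coffee 2. Brown fat genes differed by -1.43 in GTE and -1.11 in coffee (exact permutation p = 0.229 and 0.143), with Ucp1 from 0.0745 to 423 FPKM. Nociceptor genes differed by 0.99 and 1.09 (exact permutation p = 0.314 in both), with Calca from 3.19 to 75.6 FPKM. Within the chaperone list the cytosolic heat shock part differed by -0.92 in GTE (exact permutation p = 0.0286) and the endoplasmic reticulum stress part by -0.32 (p = 0.0286), against -0.27 and -0.16 in coffee (p = 0.457 and 0.143). The morning arm of the clock was at -0.44 in GTE (exact permutation p = 0.0286) and -0.45 in coffee (p = 0.0571), and the evening arm at 0.32 and 0.18 (p = 0.343 and 0.514). Among glucocorticoid response genes, Fkbp5 was at 9.93 ± 1.6 FPKM in GTE, 13.6 ± 3.996 in coffee and 19.0 ± 5.10 in control. Lcn2 also stands in the myeloid marrow list and Plin4 in the adipocyte list.

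The first principal component of the 12 libraries held 39.2% of the variance and set coffee 1 (44.4), coffee 4 (32.4) and GTE 1 (48.4) apart from the other libraries (-26.2 to -0.5). How often other splits of the same libraries gave as many calls was counted. For coffee against control, 2 of 35 splits gave at least 1 gene, the real one included, and the highest other split gave 62. Its 19 lists were reached in 10 of 35 splits, at most 23, so chance is not excluded for either count. Its 3175 genes at an unadjusted p under 0.05 were not reached by any other split (at most 2774), whereas the 1337 of GTE against control were reached in 3 of 35 (at most 1746) and the 1071 of GTE against coffee in 8 of 35 (at most 5781). For GTE against control, 1 of 35 splits, the real one, gave at least 1 gene in the main fit and the highest other gave 0. That share is the smallest that 35 splits can give and rests on Serpinh1 alone, so it does not exclude chance. With sample weights, 3 of 35 splits gave at least the 4 genes called. The Serpinh1 call was lost without any of 9 libraries, with only the 8 libraries compared, with the replicate block, with the marrow covariate and without the 3 libraries richest in marrow transcripts. Its 15 lists were reached in 18 of 35 splits, at most 19. For GTE against coffee the count was 0 in limma (1071 at an unadjusted p under 0.05), which any split reaches (35 of 35), so this count says nothing on chance. Its 16 lists were reached in 19 of 35, at most 24. Of these splits, coffee 1, 2 and 4 with GTE 1 against the remaining 4 gave 3191 genes (0 with the marrow covariate), and for coffee against control the split with 62 genes set coffee 1, 2 and 4 with control 2 against the remaining 4 (377 with the marrow covariate). Both splits differ from the real one by an exchange of 1 library per group, so they can still carry a treatment difference. They thus cannot tell another structure of the samples from the treatment. Only the first count, 3191, ended with the covariate. For any group, 9 of 100 drawn splits gave at least 1 gene, at most 3604, so chance is not excluded there.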
